A study of Macaca mulatta with 18 samples.

How the data were processed

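The series holds 18 samples of macaque fetal brain at embryonic day 84 in 10 groups: Hi-C and RNA-seq with 3 libraries per tissue, DNase-seq and CTCF ChIP-seq with 1 per tissue, and 2 CTCF input samples that were not used here. Groups and replicate numbers were taken from the sample titles. The labels do not spell out GZ and CP, and the abbreviations are kept. The submitters' processing notes name HiC-Pro, Bowtie2, STAR, SAMtools, deepTools, MACS2 and HOMER and the builds rheMac8 and Mmul_8.0.1, without roles or versions.

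RNA values are log2 FPKM that the authors had normalized with cqn, per the labels; the read counter and annotation release are not given in the sources used here. Loop lists came from HiCCUPS at 10 kb, per the labels, with 1 list per tissue for its 3 libraries, which was taken as pooled. The observed counts of contacts, the expected contacts (a signal from the donut neighbourhood) and the FDR, a kind of q-value, are per the file headers. A note of the series says that Hi-C contact files were replaced and sequencing runs added after the first deposit; whether the loop and boundary lists rest on them is not given in the sources used here. Boundary strengths are deposited scores, taken as strengths from the values since no header names the column, on 40 kb bins of rheMac8. DNase peaks of 146 bp are from HOMER, and their scores, fold over local background, normalized tag signal and p-value are per the file headers. CTCF peaks are in MACS2's narrowPeak format, with a score, a fold enrichment ratio and −log10 p and q deposited by the authors. The CTCF peak names contain the word merge, so the lists can rest on merged runs. Peak scores are the authors' own and were ranked only within a list. Medians of scores and of CTCF fold enrichment are given for both tissues without a test.

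Gene identifiers were paired with symbols through a reference table, and 14700 of 22345 (65.8%) had a symbol. SOX2, HES1 and EOMES had no symbol in that table and are not analysed here. The genome and annotation on the build of the files were not used here, so peaks, loops and boundaries were not assigned to genes, and the planned comparison of promoters with expression was not run. Coordinates are 1-based on rheMac8; DNase positions are as listed.

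Genes with a mean of 0 or more over the 6 libraries on the log2 scale were tested (13460, of which 11092 had a symbol) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with trend, GZ minus CP, without a block and without a pseudocount. Adjusted p is by Benjamini-Hochberg. Gene lists with 3 or more measured genes (23 of 24) were tested with camera at its preset correlation of 0.01. On simulated data with the means and residual SDs of the 13460 genes and 200 genes changed between GZ and CP, 67% of changes of 1 and 96% of changes of 2 on the log2 scale were recovered, with 14 false calls. The simulated noise was independent between genes, and in the data 45.4% of genes were called. These rates may thus not carry over to the real comparison. The lists, the tests, the naming rule and all alternatives except those said to be chosen later were set before the data were examined.

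Named genes are the 10 with the largest difference in each direction among those with adjusted p under 0.05, a difference of at least 1, no overlap between tissues and a symbol; up to 4 called members of each list, or the 1 or 2 with the largest difference where none was called; and 11 genes fixed in advance where measured. Some genes that this rule names are not reported here. Named loops, peaks and boundaries are the 3 highest by observed over expected contacts, caller score or strength.

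Loops were shared when both anchors lay within 1 bin, boundaries when within 40 kb, and peaks when they overlapped by at least 1 bp. Overlaps were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and checked on made-up lists with a known overlap. Co-location was compared with 100 circular shifts along each chromosome, whose length was taken as the largest coordinate in any file. Shares have 95% Wilson intervals from scipy 1.17.1, which cover counting error only. With a single list per tissue no test between tissues was made for Hi-C, DNase or CTCF data.

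Alternatives were a replicate block, other low-value filters, a pseudocount of 1, median centring, quantile normalization, other variance models, each library left out, an estimated correlation and fry for lists, other overlap rules, stricter thresholds and lists of equal length. Chosen after seeing the data were leaving out both libraries numbered 1, loops up to 2 Mb, and lists of ventral telencephalon, dorsal cortex, subplate, potassium channel, retinoic acid and Y-linked genes.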

Results

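Fetal brain of rhesus macaque at embryonic day 84 was profiled in 2 kinds of tissue that the labels call GZ and CP. RNA-seq and Hi-C had 3 libraries per tissue, and DNase-seq and CTCF ChIP-seq had 1 library per tissue. Hi-C measures how often pairs of genomic regions lie close together, DNase-seq marks open chromatin, and CTCF ChIP-seq marks sites bound by the insulator protein CTCF. The RNA table held 22345 genes as log2 normalized FPKM, with library medians between 1.82 and 1.88. Read depth was unknown for the RNA, DNase and CTCF data, since the values analysed here carry no read totals. Each tissue had 1 Hi-C list for its 3 libraries, and the median loop rested on 75 contacts in CP and 82 in GZ. Labels do not say whether libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical in part. Over 8 Y-linked genes the median log2 value was 3.34 and 3.63 in CP and GZ of number 2, and -1.78 in both of number 3. These values argue against a single animal for the RNA libraries numbered 2 and 3.

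The RNA comparison asked which genes differ between GZ and CP. Most cell cycle and primary microcephaly genes were higher in GZ, and most genes of neuronal maturation and of blood vessels were higher in CP. Of 13460 genes tested with limma, 3297 were higher in GZ and 2816 higher in CP at an adjusted p under 0.05. Genes called in either direction made up 45.4% of those tested, so list counts near that share are not particular to a list. At least 2-fold differences were found for 728 genes higher in GZ and 948 higher in CP, or 481 and 729 with a pseudocount of 1, which shrinks the differences of low genes. The 3 GZ and 3 CP values did not overlap for 56.4% of genes, against 10% by chance. Correlations of library profiles ran from 0.971 to 0.987 within a tissue and from 0.895 to 0.935 between tissues. Leaving out both libraries numbered 1, whose Y-linked genes differed from each other, gave 1647 and 1716 genes.

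HELT, a basic helix-loop-helix transcription factor, had the largest named difference in favour of GZ, with 13.4-fold higher RNA (log2 difference 3.74 ± 0.76 SE, adjusted p = 0.0056, n = 3 per tissue). On the log2 scale HELT was -1.55 ± 1.15 in CP and 2.19 ± 1.36 in GZ (SD), so its fold rests on low CP values. NKX2-1, a homeobox factor of the ventral forebrain, was 10.5-fold higher (3.39 ± 0.62, adjusted p = 0.0035). CRABP1, which binds retinoic acid inside cells, was 9.77-fold higher (3.29 ± 0.46, adjusted p = 0.0012). The cell cycle transcription factor E2F2 was 8.41-fold higher, the zinc finger factor SP9 7.11-fold and the vesicular monoamine transporter SLC18A2 7.10-fold higher in GZ. CDCA7, TROAP and ANKLE1 were 6.01-fold, 5.93-fold and 5.88-fold higher. CP means on the log2 scale were also low for NKX2-1 (0.09), E2F2 (-0.05) and ANKLE1 (-0.28). The retinoid receptor gene RXRG was 5.83-fold higher (adjusted p = 0.019). The RXRG call was lost without CP replicate 2, CP replicate 3 or GZ replicate 1, with limma adjusted p of 0.060, 0.066 and 0.058.

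The 10 largest named differences in favour of CP ran from 13.8-fold to 29.96-fold. ACTN2, which codes for an actin cross-linking protein, was 29.96-fold higher in CP (6.27 ± 0.27 against 1.37 ± 0.34 on the log2 scale, SD, n = 3, adjusted p = 9.93e-06). POSTN, which codes for the matrix protein periostin, was 28.1-fold higher in CP (4.04 ± 0.81 against -0.77 ± 0.60, adjusted p = 1.89e-04). The kelch family genes KLHL1 and KLHL4 were 24.9-fold and 23.2-fold higher, and TAFA1, which codes for a secreted protein, was 24.0-fold higher. NWD2 was 20.0-fold and the adhesion molecule gene CNTN6 17.3-fold higher in CP. GRP, the gene of gastrin-releasing peptide, was 14.3-fold higher, the muscarinic receptor gene CHRM3 13.9-fold and FRMPD4 13.8-fold. GZ means on the log2 scale were low for KLHL4 (-0.52), CNTN6 (-0.64), CHRM3 (-0.46), TAFA1 (0.21) and NWD2 (0.44). They were also low for FRMPD4 (0.57), KLHL1 (0.66) and GRP (0.66). The folds of these genes and of POSTN thus rest on low GZ values.

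Proliferation genes were mostly higher in GZ. In the cell cycle list 18 of 19 measured genes were higher in GZ and PLK1 did not pass (0.21 ± 0.08 SE, adjusted p = 0.054). Adjusted over the list alone, all 19 were higher in GZ. MKI67, a proliferation marker, was 4.24-fold higher (log2 difference 2.08 ± 0.28, adjusted p = 9.27e-04), the cyclin gene CCNB2 4.21-fold, the mitotic kinase gene AURKB 3.95-fold and TOP2A 3.88-fold. Of 14 genes mutated in primary microcephaly, 12 were higher in GZ, and 13 when adjusted over the list alone. KNL1, KIF11, CEP152 and NDE1, which act at kinetochores, spindles or centrosomes, were 3.84-fold, 3.61-fold, 3.37-fold and 3.14-fold higher. Both lists passed limma camera (adjusted p = 7.12e-07 and 9.86e-05), and both calls were lost with an estimated correlation (adjusted p = 0.632 with an estimated correlation for each).

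Markers of neural progenitors went both ways. Of 8 ventricular radial glia genes, 4 were higher in GZ, 1 was higher in CP and 3 did not pass; adjusted over the list alone the counts were 5 and 2. PAX6, a transcription factor of cortical progenitors, was 1.98-fold higher in GZ (0.98 ± 0.19, adjusted p = 0.0050), GLI3 2.83-fold and NOTCH1 2.59-fold. PROM1, which codes for a membrane protein of apical progenitors, was 3.98-fold higher in CP (log2 difference, GZ minus CP, -1.99 ± 0.20). In the outer radial glia list MOXD1 was 2.93-fold higher in GZ and HOPX was 1.59-fold higher in CP (-0.67 ± 0.13, adjusted p = 0.0040). That list had 2 genes higher in GZ, 1 higher in CP and 6 not passing, the same when adjusted over the list alone, and its median (-0.15) and mean (0.06) differed in sign. Without GZ replicate 3 the outer radial glia counts were 1 higher in GZ and 4 higher in CP, without CP replicate 3 they were 1 and 2, and without CP replicate 2 or GZ replicate 2 they were 1 and 1. The ventricular list had 2 genes higher in CP without CP replicate 3. Of 6 intermediate progenitor genes 3 were higher in GZ, also when adjusted over the list alone: NHLH1 (3.86-fold), PPP1R17 (1.78-fold) and HES6 (1.56-fold). PPP1R17 was not called by limma without CP replicate 2, CP replicate 3, GZ replicate 1 or GZ replicate 3 (adjusted p = 0.086, 0.108, 0.068 and 0.059). In the Notch pathway list 6 of 11 genes were higher in GZ and 2 higher in CP, or 6 and 3 when adjusted over the list alone, and 1 was higher in CP without CP replicate 1, CP replicate 3, GZ replicate 1 or GZ replicate 2. The Notch ligand genes DLL1 and DLL3 were 3.54-fold and 2.96-fold higher in GZ. None of these 4 lists passed limma camera (adjusted p = 0.512, 0.742, 0.099 and 0.427), and without GZ replicate 2 the intermediate progenitor list did (adjusted p = 0.039).

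Genes of mature neurons were mostly higher in CP. Of 19 neuronal maturation and synapse genes 17 were higher in CP, also when adjusted over the list alone, and GRIA2 and SLC17A6 did not pass. The neurofilament genes NEFL and NEFM were 10.4-fold and 6.58-fold higher, the glutamate receptor gene GRIN2B 7.20-fold and CAMKV 4.83-fold. SYT1, the calcium sensor of synaptic vesicles, was 1.77-fold higher in CP (-0.82 ± 0.13, adjusted p = 0.0018). The list passed camera (adjusted p = 2.05e-09), and the call was lost with an estimated correlation (adjusted p = 0.598 with an estimated correlation). Among 8 upper-layer neuron genes 5 were higher in CP and 1 higher in GZ, or 5 and 2 when adjusted over the list alone; none was higher in GZ without CP replicate 1, CP replicate 2, GZ replicate 1 or GZ replicate 3. LHX2, a LIM homeobox transcription factor, was 2.14-fold higher in CP (-1.10 ± 0.12, adjusted p = 4.33e-04) and RORB, a nuclear receptor gene, 1.89-fold.

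Deep-layer genes split. Of 12 measured, 5 were higher in CP, 1 was higher in GZ and 6 did not pass, also when adjusted over the list alone, and 2 were higher in GZ without GZ replicate 3. FEZF2, a factor of subcortical projection neurons, was 5.53-fold higher in CP (-2.47 ± 0.17), NR4A2 2.85-fold and LDB2 2.41-fold. BCL11B, which marks subcortical projection neurons and also striatal neurons, was 3.36-fold higher in GZ (1.75 ± 0.15, adjusted p = 1.63e-04). TBR1 was 5.80 ± 0.34 in CP and 5.11 ± 0.87 in GZ (SD, n = 3, adjusted p = 0.184). Without GZ replicate 3 the TBR1 difference was -1.18 with a limma adjusted p of 0.0037. Neither layer list passed camera (adjusted p = 0.130 and 0.097).

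Interneuron genes were mostly higher in GZ. Of 11 measured, 6 were higher in GZ, 1 was higher in CP and 4 did not pass, also when adjusted over the list alone. DLX6, a homeobox gene of ventral forebrain progenitors, was 4.92-fold higher in GZ, SCGN 4.80-fold and GAD2, which codes for a GABA-synthesizing enzyme, 4.00-fold (2.00 ± 0.21, adjusted p = 3.68e-04). SST, the gene of the neuropeptide somatostatin, was 3.35-fold higher in CP (-1.74 ± 0.35). The list passed camera (adjusted p = 0.030), and the call was lost with an estimated correlation (adjusted p = 0.601 with an estimated correlation).

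Blood vessel genes were higher in CP, including 9 of 10 without both libraries numbered 1. All 10 measured endothelium and pericyte genes were higher in CP, also when adjusted over the list alone, with FLT1 and KDR, receptors for vascular growth factor, 4.27-fold and 4.06-fold higher, RGS5 3.60-fold and CDH5 3.21-fold. In the extracellular matrix and integrin list 8 of 18 genes were higher in CP and 1 higher in GZ, or 9 and 1 when adjusted over the list alone, and none was higher in GZ without any 1 of the GZ replicates. The members with the largest differences, LAMA4 (3.76-fold), NID1 (3.10-fold) and LAMA2 (2.98-fold), code for basement membrane proteins, and the vessel markers were also higher in CP. Both lists passed camera (adjusted p = 9.86e-05 and 0.030), and both calls were lost with an estimated correlation (adjusted p = 0.632 and 0.657 with an estimated correlation). The matrix call was also lost without CP replicate 1 (adjusted p = 0.054) or CP replicate 3 (adjusted p = 0.080), and without both libraries numbered 1 (adjusted p = 0.077).

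The called genes of chromosome folding were higher in GZ. In the chromatin architecture list 8 of 13 genes were higher in GZ and none was higher in CP, or 8 and 1 when adjusted over the list alone. ZNF143 was 1.78-fold, the cohesin gene SMC1A 1.74-fold and the cohesin loader gene MAU2 1.56-fold higher. CTCF itself was 5.70 ± 0.16 in CP and 5.93 ± 0.05 in GZ (SD, n = 3, adjusted p = 0.085). Leaving out CP replicate 1 gave CTCF a limma adjusted p of 0.047. The list passed camera (adjusted p = 0.030), and the call was lost with an estimated correlation (adjusted p = 0.657 with an estimated correlation), without CP replicate 2 (adjusted p = 0.055) and without GZ replicate 3 (adjusted p = 0.059). Without CP replicate 2, CP replicate 3, GZ replicate 1 or GZ replicate 3, 5 of the 13 genes were higher in GZ, with 1 higher in CP without CP replicate 3, and without both libraries numbered 1 the count was 3.

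In the other lists the counts were the same when adjusted over the list alone except where given. Axon guidance genes split into 7 higher in GZ and 6 higher in CP out of 27, with UNC5C 6.40-fold and EPHA7 3.35-fold higher in CP and PLXNA2 2.28-fold higher in GZ. RELN, the reelin gene, was 2.17-fold higher in CP and was the called gene of the 3 Cajal-Retzius genes. In the oligodendrocyte list 2 of 5 genes were higher in GZ, among them MBP (1.82-fold), or 1 without CP replicate 3, and CSPG4 was 2.22-fold higher in CP. Among 6 astrocyte genes SPARCL1 was 2.38-fold higher in CP and GLUL 1.32-fold higher in GZ, and 2 were higher in CP without GZ replicate 2. None of 6 microglia genes passed in limma, with TYROBP 0.44 ± 0.37 and C1QC -0.30 ± 0.20 (log2 difference, SE). Without both libraries numbered 1, 3 of them were higher in GZ, among them TYROBP (1.10, adjusted p = 0.025), and the median of the list was 0.63 against 0.15. None of 7 meningeal and fibroblast genes passed in limma (LUM -1.07 ± 0.39, adjusted p = 0.054), although LUM passed without CP replicate 1 (adjusted p = 0.014) or GZ replicate 3 (adjusted p = 0.029). Without GZ replicate 3, 2 meningeal genes were higher in CP, and 1 was higher in GZ without CP replicate 3 or GZ replicate 2. FOXJ1 was the measured gene of choroid plexus and ependyma (adjusted p = 0.815). ALAS2 was 1.69-fold higher in CP among 2 called of 4 erythroid genes. The other, HBA, was not called by limma without CP replicate 1, CP replicate 2, CP replicate 3 or GZ replicate 1 (adjusted p = 0.071, 0.057, 0.054 and 0.066), and neither was called without both libraries numbered 1 (ALAS2 adjusted p = 0.058). FOS was 2.35-fold higher in GZ among 2 called of 6 immediate early genes, with 1 called without GZ replicate 2 and 4 without GZ replicate 3, where the list passed camera (adjusted p = 0.043). Of 10 hypoxia and glycolysis genes 4 were higher in CP, among them SLC2A1 (1.89-fold), and 1 was higher in GZ, or 2 when adjusted over the list alone. The gene higher in GZ, PDK1 (1.43-fold), was not called by limma without CP replicate 1, CP replicate 2, GZ replicate 1 or GZ replicate 2 (adjusted p = 0.063, 0.090, 0.126 and 0.083). Without both libraries numbered 1, 2 genes of that list were higher in CP and 0 in GZ. Among 9 housekeeping genes HPRT1 was 1.73-fold higher in CP and ACTB 1.56-fold higher in GZ, with 1 gene higher in GZ and 2 in CP, or 1 in CP without any 1 of the CP replicates. ACTB was not called without both libraries numbered 1 (adjusted p = 0.086).

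**Figure D1:**
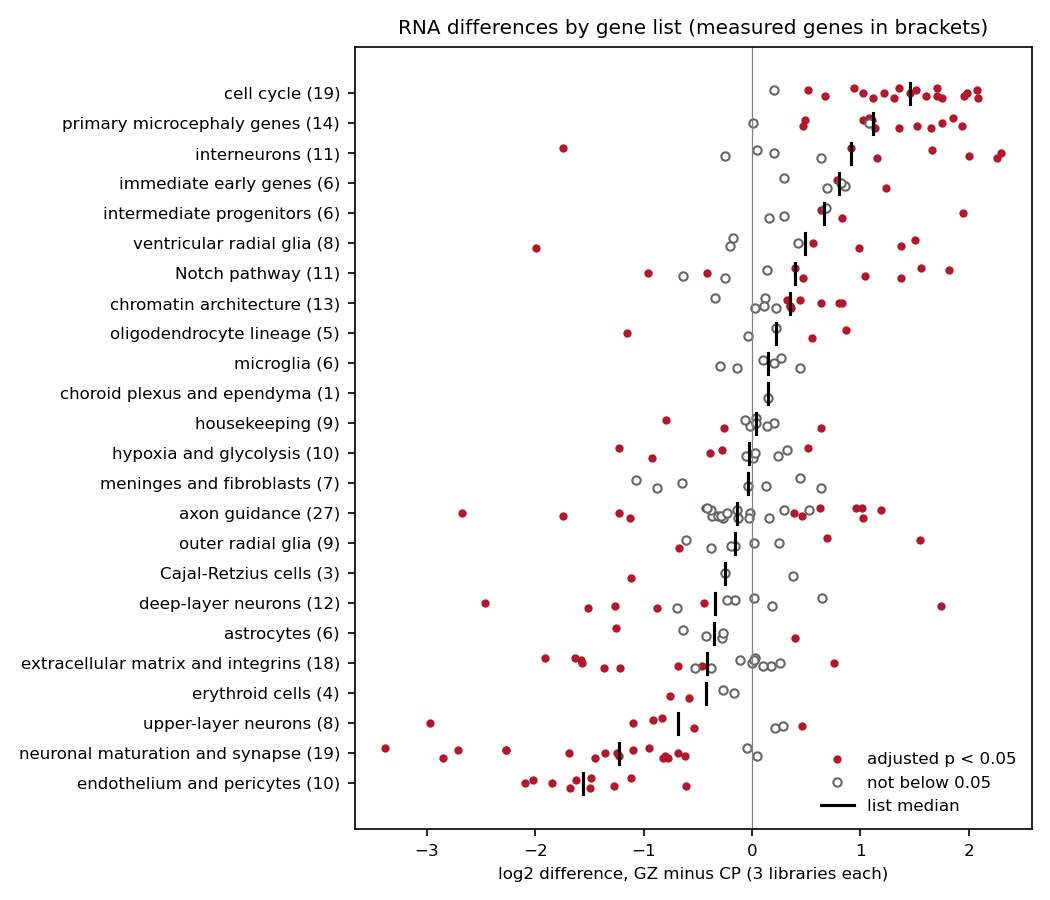
Each point is a measured gene of a list, placed by its log2 difference between GZ and CP (horizontal axis, 3 libraries per tissue), with filled points for adjusted p under 0.05, open points for the rest and a black bar at the list median. The cell cycle median lies at 1.46 and the endothelium and pericyte median at -1.56.

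**Figure D2:**
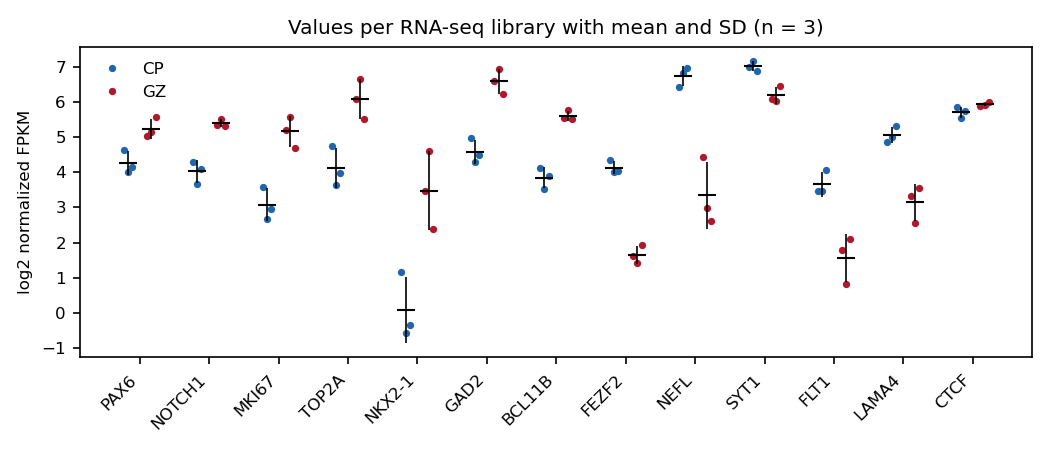
Points are the log2 normalized FPKM values (vertical axis) of 3 CP and 3 GZ libraries for 13 genes, with a dash at the mean and a line for the SD. MKI67 averages 3.07 in CP and 5.16 in GZ, and CTCF 5.70 and 5.93.

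The Hi-C comparison asked which chromatin loops are found in both tissues. The CP list held 9399 loops and the GZ list 15048, at 10 kb resolution on rheMac8. Of CP loops 80.8% had a GZ loop with both anchors within 1 bin (7596 loops, 95% Wilson interval 80.01% to 81.6%), and of GZ loops 50.5% had a CP loop (49.7% to 51.3%). Circular shifts of the positions gave 0.307% and 0.198% on average. The lists differ in length, and with both at 9399 loops the shares were 62.4% and 62.3%. The GZ loops kept for this were those with the highest observed over expected contacts. This ranking favours long loops: in GZ the median ratio was 51.3 over 10 Mb and 3.51 at 1 to 2 Mb. Each tissue has a single pooled list, so no difference between tissues was tested, and intervals cover counting error only.

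At the 5563 loops called in the same bins in both lists, observed over expected contacts had a median of 3.47 in CP and 4.03 in GZ. The GZ to CP ratio had a median of 1.13 and was above 1 at 72.9% of these loops. The GZ to CP ratio of expected contacts at the same bins had a median of 1.23. Loops spanned a median of 540 kb in CP and 560 kb in GZ.

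The named loops with the highest observed over expected contacts spanned more than 10 Mb. The strongest shared loop in CP joined chromosome 5 positions 31760001 to 31770000 and 164120001 to 164130000 with 8932 contacts observed and 1.19 expected. It also ranked among the strongest 3 in GZ, with 8355 contacts observed and 1.33 expected. The strongest shared loop in GZ lay on chromosome 14, between 8730001 to 8740000 and 61360001 to 61370000, with 1218 contacts. Among loops found in CP alone, the highest ratio belonged to chromosome 2, 90060001 to 90070000 with 175760001 to 175770000, which had 13 contacts. In GZ alone it was chromosome 14, 9430001 to 9440000 with 99520001 to 99530000, which had 26 contacts. Neither anchor of the chromosome 5 loop held a CTCF peak in CP or in GZ. Loops over 10 Mb made up 17.3% of the CP list and 15.0% of the GZ list. Their observed over expected contacts had a median of 54.9 in CP and 51.3 in GZ. Bins with extreme read pile-ups may be a source of such contacts, as described under the other observations, so their rank may not reflect chromatin looping. Among loops up to 2 Mb, a limit chosen after the values were seen, a shared loop on chromosome X between 52120001 to 52130000 and 52580001 to 52590000 was strongest in both lists, with 47 contacts in CP and 58 in GZ.

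CTCF peaks lay at many loop anchors. In CP 37.7% of loops had a CTCF peak of the same tissue in both anchors (36.8% to 38.7%), against 0.841% ± 0.135 (SD) over 100 circular shifts. In GZ the share was 48.6% (47.8% to 49.4%), against 1.47% ± 0.17. Of all anchors, 52.8% held a CTCF peak in CP and 62.5% in GZ, against 7.78% and 10.6% after shifting. The GZ list of CTCF peaks was longer; shortened to the length of the CP list, it gave 39.3% of GZ loops with CTCF in both anchors. DNase peaks lay in 68.7% of CP anchors and 73.7% of GZ anchors, against 21.5% and 24.6% after shifting. GZ loops absent from the CP list had CTCF in both anchors in 45.4% of cases, and those also in the CP list in 51.8%. For CP the shares were 22.6% and 41.3%. These contrasts were not adjusted for distance. Each tissue's own CTCF list was used at full length, so CP and GZ shares here also differ by list length. Loops over 10 Mb, few of which had CTCF in both anchors, were shared in 67.9% of cases in CP against 80.8% of all CP loops. In GZ the values were 49.2% and 50.5%.

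The share depended on distance. Of loops spanning 100 kb or less, 30.6% in CP and 42.5% in GZ had CTCF in both anchors, and of loops up to 2 Mb together, 47.6% and 58.8%. Over 10 Mb the shares were 1.29% (0.845% to 1.96%) of 1628 loops in CP and 1.91% (1.42% to 2.56%) of 2250 loops in GZ.

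**Figure D3:**
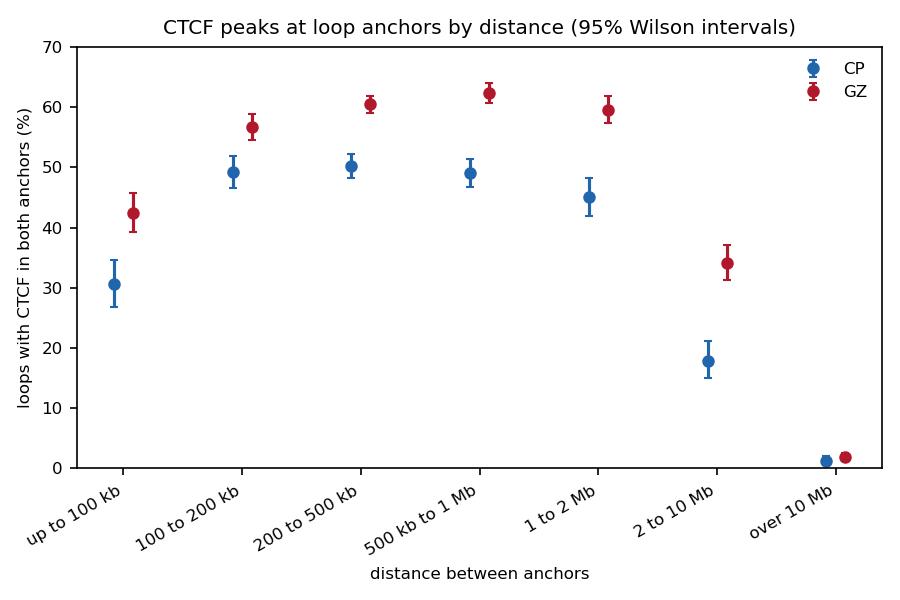
Points give the percentage of loops with a CTCF peak in both anchors (vertical axis) by distance between anchors (horizontal axis, 7 classes) for CP and GZ, with 95% Wilson intervals as bars. Both tissues stay above 30% up to 2 Mb and fall to 1.29% and 1.91% over 10 Mb.

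Boundaries between insulated domains were mostly found in both tissues. Of 2584 CP boundaries, 91.7% had a GZ boundary within 40 kb (90.6% to 92.7%), and of 2806 GZ boundaries 84.8% had a CP boundary (83.4% to 86.1%), against 18.9% and 17.5% after shifting. With at least 1 bp of overlap the shares were 57.2% and 52.7%. Boundaries found in GZ alone had a median strength of 0.363, and shared GZ boundaries 0.673. The strongest boundaries found in CP alone lay on chromosome 19, at 23040001 to 23080000 and 23080001 to 23120000 (strengths 2.16 and 2.14), and on chromosome 17 at 94320001 to 94360000 (0.983). In GZ alone they lay on chromosome 2 at 91760001 to 91800000 (1.19), chromosome 10 at 22400001 to 22440000 (1.17) and chromosome 6 at 138440001 to 138480000 (1.06). A CTCF peak lay within 20 kb of 68.7% of CP boundaries and 75.7% of GZ boundaries, against 38.5% ± 1.0 and 48.8% ± 0.8 after shifting. With CTCF lists of equal length the GZ share was 65.6%.

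Open chromatin was partly shared between the lists. Of 71800 CP DNase peaks 61.6% overlapped a GZ peak (61.2% to 61.9%), and of 83028 GZ peaks 53.3% overlapped a CP peak (52.9% to 53.6%), against 0.895% and 0.770% after shifting. Shared peaks had a median caller score of 24 in CP and 26 in GZ, and peaks of a single list 12.5 and 13.5, by the authors' scores. The highest scores among peaks in CP alone were 417.5 and 406.5, both on the mitochondrial genome, and 407.5 on chromosome 12 at 94712528 to 94712674. In GZ alone they were 2327 on chromosome 2 at 130167133 to 130167279, 1391.5 on the mitochondrial genome and 1378 on chromosome 9 at 102918366 to 102918512.

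Most CP CTCF peaks were also in the GZ list. Of 22044 CP peaks 91.5% overlapped a GZ peak (91.1% to 91.9%), and of 30883 GZ peaks 65.1% overlapped a CP peak (64.6% to 65.7%), against 0.839% and 0.596% after shifting. With both lists at 22044 peaks the shares were 79.9% and 79.5%. The authors' fold enrichment had a median of 7.03 in CP and 13.8 in GZ. With 1 library per tissue and unknown depth, this difference cannot be told apart from one between the libraries. DNase peaks overlapped 75.9% of CP and 68.3% of GZ CTCF peaks. In GZ that share was 81.4% for shared CTCF peaks and 44.0% for those of GZ alone. In CP it was 77.3% for shared CTCF peaks and 61.3% for those of CP alone. CTCF peaks of GZ alone had a lower median fold enrichment than shared ones (8.66 against 17.5), as did those of CP alone (6.51 against 7.09). The shares were not adjusted for peak strength. The highest scores among peaks in CP alone lay on chromosome 7 at 85526639 to 85527060 (603), chromosome 3 at 63575933 to 63576292 (573) and chromosome 5 at 9081818 to 9082237 (552). In GZ alone they lay on chromosome 11 at 94895487 to 94895890 (2555), chromosome 10 at 84016288 to 84016659 (2464) and chromosome 1 at 2520786 to 2521200 (2359).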

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

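Leaving out both RNA libraries numbered 1 and keeping only loops up to 2 Mb were chosen after the results were seen. The count of changed RNA genes was 6113 and lay between 5764 and 6222 under the other filters, scalings and variance models. Leaving out 1 library gave 4504 to 6001 genes, with 2261 to 3146 higher in GZ and 2243 to 2855 higher in CP. For at least 2-fold changes the range was 1518 to 1793, with 624 to 799 higher in GZ and 885 to 997 higher in CP. Without both libraries numbered 1 there were 3363 genes, 1647 higher in GZ and 1716 in CP, with fewer samples. With a pseudocount of 1, which shrinks changes of low genes, 481 genes were at least 2-fold higher in GZ against 728.

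With the replicate number as a block 6117 genes were called, 5769 of them also without it (3300 higher in GZ, 2817 in CP; 1692 at least 2-fold, 737 and 955), and 9 lists against 7, the intermediate progenitor (adjusted p = 0.032) and immediate early lists (adjusted p = 0.014, 5 of 6 genes called against 2) being added. In that fit LUM was called by limma (adjusted p = 0.036) and PDK1 was not (adjusted p = 0.052). The meningeal and fibroblast list had 1 gene higher in GZ and 2 higher in CP. The labels do not say that numbers mark animals. Deviations of same-numbered libraries correlated at -0.381, 0.299 and 0.347. The libraries numbered 2 and 3 correlated best with their own number. Those numbered 1 did not, so the numbers were not taken as pairing for the set of libraries.

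Of 23 gene lists, 7 passed camera, 6 to 8 with 1 library left out, 12 with fry and 0 with an estimated correlation, where 1 had an unadjusted p under 0.05; the cause was not tested. Without a filter on low values 10 lists passed, the upper-layer (adjusted p = 0.020) and deep-layer lists (adjusted p = 0.012) among them. Of 1466 values of 98 named genes under 15 alternatives, 52 lost the call, 7 gained it and 0 reversed.

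Loop sharing, for CP and GZ, was 59.2% and 37.0% in the same bins, 84.7% and 52.9% within 2 bins, 62.4% and 62.3% at equal list lengths, and 83.9% of CP loops up to 2 Mb. Boundary sharing was 57.2% and 52.7% by overlap, 93.8% and 87.3% within 80 kb, and 89.9% and 82.9% for boundaries of at least median strength. DNase sharing was 55.7% and 48.2% at 50% reciprocal overlap, 68.6% and 59.2% from the median score, and 58.4% for both at equal lengths. CTCF sharing was 88.1% and 62.9% at 50% reciprocal overlap and 79.9% and 79.5% at equal lengths. Loops with CTCF in both anchors came to 54.7% and 67.7% with anchors widened by 1 bin and 47.6% and 58.8% up to 2 Mb, and 39.3% in GZ at equal CTCF lists. Single anchors with CTCF came to 66.7% and 77.0%, 64.9% and 73.5%, and 55.5% in GZ. Boundaries with CTCF came to 81.5% and 87.7% within 40 kb, and 65.6% in GZ at equal CTCF lists. Anchors with DNase came to 53.6% and 59.8% from the median score, 73.7% and 79.9% up to 2 Mb, and 71.5% in GZ at equal lists. The cause was not tested beyond what each rule changes. The planned promoter alternatives were not run. Depth is unknown for peaks, so differences in list length cannot be separated from depth.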

Other observations

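The tests of this part were chosen after the results were seen, except the splits of the RNA libraries and the test of ventral genes not yet looked at. Potassium channel genes were mostly higher in CP. Of 14 measured, 9 were higher in CP and 2 higher in GZ, and the 13 not looked at before the list was made had a median log2 difference, GZ minus CP, of -0.75. Those 13 passed limma camera (adjusted p = 0.038 over 4 lists), a call lost with an estimated correlation (adjusted p = 0.503 with an estimated correlation). KCNQ5, which codes for a channel of the M current, had the largest difference (-3.59), and KCNMA1, a calcium-activated channel gene, had -1.92. Of 5 subplate genes 3 were higher in CP, among them NR4A2 (-1.51) and CPLX3 (-1.75), and of 5 dorsal cortex genes 4 were higher in CP, among them NEUROD1 (-1.26) and NEUROD6 (-3.25). Of these, 2 subplate genes, NR4A2 among them, and 3 dorsal cortex genes, NEUROD6 among them, had been looked at before listing. The 3 unseen subplate genes did not pass camera (adjusted p = 0.098), and the 2 unseen dorsal cortex genes were too few for that test.

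Retinoic acid genes went both ways. Of 12 measured, 5 were higher in GZ and 2 higher in CP in limma, and the 10 not looked at before did not pass camera (adjusted p = 0.640). RARA, a receptor gene, had a log2 difference of 1.17, while CYP26A1, which codes for a retinoic acid-degrading enzyme, had -2.81 and STRA6, a retinol uptake gene, -1.95.

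The real split of the 6 RNA libraries called 6113 genes and the highest of the other 9 splits called 0 in limma, where 20 to 710 genes had an unadjusted p under 0.05. The 10 splits into 3 and 3 are too few for a share under 0.05.

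Y-linked genes split the 2 RNA libraries numbered 1. Over 8 Y-linked genes the median log2 value was 3.34 and 3.63 in CP and GZ of number 2, -1.78 in both of number 3, and 1.40 in CP against -0.17 in GZ of number 1. A candidate explanation is that the libraries numbered 1 did not come from the same animals: the median CP minus GZ difference was 1.71 within number 1 (-1.35 to 4.68 over the genes), against -0.40 and -0.14 within numbers 2 and 3. Swapped tissue labels within number 1 would only change the sign of this difference, so they could not explain it. That swap is 1 of the other 9 splits above and called 0 genes in limma, with 395 genes at an unadjusted p under 0.05. This argues against mislabelled tissues but has no bearing on why the Y-linked genes differ. Number 1 reached 35.8% of the number 2 level in CP and 8.55% in GZ, against 2.70% and 2.87% for number 3. A mixed sample thus stays open, and no biological explanation was tested. None of 7 tested Y-linked genes was called between GZ and CP. The DNase lists titled with number 1 had 2 peaks on chromosome Y in CP and 41 in GZ, and the CTCF lists 6 and 13. Both run opposite to the RNA of number 1, where the Y-linked median was higher in CP.

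Part of the contacts called over more than 10 Mb recurred at the same bins. Of the 1573 bins used in CP and 2425 in GZ, those used by 5 or more such loops numbered 88 and 86 and held 43.2% and 37.8% of their anchor places, led by chromosome 1 at 70030001 to 70040000 with 291 and 416 loops. Pairs of CTCF sites are argued against: the share with CTCF in both anchors was at most 0.0325 times that of loops up to 2 Mb. Bins with extreme read pile-ups may be a source, since the 100 most duplicated nuclear DNase peaks lay in these anchors at least 9.48 times as often as other peaks (19% against 0.836% in CP, 10% against 1.06% in GZ). The 100 highest-scoring other peaks lay there 7.24 times as often in CP and 0.948 times in GZ, so strong peaks alone stay open in CP, and no biological explanation other than CTCF pairs was tested.

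Ventral telencephalic genes were often high in GZ: 11 of 15 measured were higher in GZ and 2 higher in CP, but 7 of the 15 were listed after being seen high in GZ, and the 8 others (4 higher in GZ, 2 in CP) did not pass limma camera (adjusted p = 0.588), with 2 of the listed genes also in the interneuron list. Cells from ventral telencephalon in the GZ libraries may contribute, but the test on 8 genes not looked at before gave a median log2 difference of 0.46 ± 0.41 (SE over genes), below the 0.5 set in advance as speaking against it by less than that error; the demand that a value pass its bound by more than its error was added after this value was seen. SOX6 (1.42) was among 4 of the 8 higher in GZ, and ZIC1 (-1.34) and ZIC4 were higher in CP. A lower share of the main cell type alone would raise markers of every other cell type alike, taken as medians within 0.5. That limit was set after the results were seen. The median of the 8 unseen ventral genes lay 2.02 above that of endothelium and pericyte genes. The median of all 15, the 7 seen ones included, lay 3.22 above it. This comparison was put in place of one with the microglia median after that one was seen. There the unseen ventral genes lay 0.31 higher, within the limit that goes with the explanation. The explanation is thus argued against for endothelium and pericyte markers only, whose median was -1.56, and not for microglia markers. Medians of other lists lay closer to the unseen ventral median. They were 0.22 for oligodendrocyte, -0.04 for meningeal and fibroblast, -0.35 for astrocyte and -0.42 for erythroid genes. Since the endothelium and pericyte list was chosen after the results were seen, no verdict on the explanation as a whole is drawn. Ventral cells and a difference between the tissues themselves cannot be told apart here. The most abundant listed genes, SP9 at 7.56, LHX6 at 7.45 and MAF at 7.17 in GZ, are also expressed in migrating interneurons. GZ libraries also differed from each other. In GZ replicates 1, 2 and 3, NKX2-1 was 3.46, 4.60 and 2.38. The dorsal cortex gene NEUROD2 ran the other way (6.09, 5.47 and 7.13). MKI67 ran like NKX2-1 (5.20, 5.57 and 4.70), and SP9 did not (7.44, 7.62 and 7.62). Whether the regional content of the libraries differed was not tested.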
